A study of Mus musculus with 398 samples.

How the data were processed

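Single nuclei of the mouse cochlear nucleus were profiled with 10x Genomics 3′ chemistry (v3), and patch-clamped cells with Smart-seq2. Per the labels there are 11 single-nucleus samples and 387 patch-seq cells. The matrices of 9 single-nucleus libraries were analysed, and those of p2s1 and p2s2 were not analysed here. The deposited values are counts, of UMIs for nuclei and of reads without molecular identifiers for cells, as whole numbers with no normalization. According to the submitters' processing notes, Cell Ranger 5.0.1, STAR 2.7.7a and featureCounts (no version given) were used with build GRCm38. Gene positions came from the GENCODE annotation of that build.

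The p and s codes in the library titles were not explained. Libraries that share a p code resembled each other far more than other pairs, with a chi-square per degree of freedom of 2.89 to 5.93 in 3 such pairs and 37.8 to 505 in the other 33 pairs. The labels name no animals, and libraries of one p code may be technical replicates, so p-values measure only the spread between libraries. An alternative sums libraries by p code.

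Barcodes with under 500 genes (1866) or over 5% mitochondrial counts (335 of the rest) were left out, which kept 76484 of 78685. Scrublet, as implemented in scanpy 1.11.5, scored doublets within each library. Its automatic threshold called under 0.5% of nuclei in 3 libraries, so after those calls were seen the highest scores were called instead, at 0.8% per 1000 barcodes, 6130 nuclei or 8.01% in all. This left 70354 nuclei. All barcodes together held 414250237 UMIs, 18887956 to 92951524 per library, with library medians of 3152 to 4540 UMIs and 1638 to 2225 genes per barcode.

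Clusters and tests used different genes. Clustering drew on cell type markers and on genes outside the fixed lists whose Ensembl number is odd, and tests on list genes and genes with an even number, 16276 of 32285. The 2000 most variable genes were scaled to z-scores within each library. They gave 50 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 with seed 1 (leidenalg 0.10.2). Clusters were named by thresholds on the CPM of fixed markers. The markers were chosen before the data were examined, as were the lists, comparisons, tests, the rule for named genes and the alternatives, except those said to be added. The thresholds were set after seeing the data, and classes are called bushy-like, octopus-like and so on for that reason. They left 3.45% ± 0.707 of nuclei with no type (mean ± SD, n = 9 libraries) and 8.31% ± 8.67 in mixed clusters. A further 3.01% ± 1.36 were inhibitory and 2.11% ± 1.14 glutamatergic without a type. All were kept out of the classes named for a type. The inhibitory nuclei without a type did enter the pools of inhibitory and of other inhibitory nuclei that were compared.

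UMIs were summed by class and library where both classes had at least 10 nuclei, in at least 3 libraries. Both sums of a pair come from the same library, so library was a block in the model. edgeR 4.0.16 fitted quasi-likelihood models with TMM scaling after filterByExpr, with Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05 and a log2 fold change of at least 1 either way. Levels of genes in the comparisons are CPM, counts scaled to the TMM-adjusted total of the class in a library, as mean ± SD over libraries. Summed markers of other cell types and the Hox and En2 levels were scaled to the total without TMM. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. The 22 lists with 328 genes cover AMPA, NMDA with kainate and delta, metabotropic glutamate, GABA and glycine receptors, Kv1, Kv2 with Kv3, Kv4, Kv7 with EAG family, calcium- and sodium-activated, and leak with inward rectifier potassium channels, HCN, sodium and calcium channels, neurofilaments, perineuronal nets, axon guidance, synaptic adhesion, vesicle release, neuropeptides, immediate early genes and Hox genes. The lists also hold partner genes, such as Lgi1 for Kv1, Kcnip4 for Kv4, Homer1 for metabotropic glutamate and Shisa9 for AMPA receptors. The leak list includes Nalcn, a sodium leak channel gene. Counts of the genes of a list include such members. Camera called 33 of 119 pairs of list and comparison, and 2 of them also with an estimated correlation. Fry, which does not compare a list with other genes, called 15 of 20, 14 of 19, 12 of 19, 19 of 21, 15 of 21 and 18 of 19 lists in the order of the report.

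Named genes were, for each list, the 2 called genes with the largest fold change among those with at least 10 CPM in the higher class and the same direction in every library, and outside the lists the 5 highest and 5 lowest such genes, without unnamed gene models. This gave 271 pairs of gene and comparison, 175 genes in all, some of which are not reported here. Genes with no count in a class are given as a bound against 3 counts over the group, and genes with 1 to 3 counts as a ratio with an exact 95% interval. The table of other cell types' markers and the genes of the unipolar brush-like clusters were chosen after their values were seen. On simulated data with the same sums, edgeR called 92 to 99 of 100 genes changed 3-fold and 99 or 100 of 100 changed 6-fold.

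All 387 patch-seq cells passed a minimum of 1000 genes. Each was given the neuron or glial class with the highest Spearman correlation over the clustering genes, and in an alternative over markers with 300 variable genes. A further alternative, added after seeing the data, had each gene centred and neuron classes only. The first assignment and the one with markers gave 181 cells the same class. Reads were summed by class. Intervals are exact Poisson for sums and Clopper-Pearson for shares, and leave out the spread between cells. The Poisson intervals treat reads as independent. Reads copied from the same molecule are not, so these intervals are too narrow even for counting error. Alternatives covered scaling by DESeq2 1.42.0 size factors, its Wald test, no low-count filter, no library block, p codes summed, at least 1000 genes, doublets kept, resolution 2, thinning to 1000 UMIs, at least 30 nuclei and leaving out each library. Added after seeing the data were leaving out both p3 libraries, counting the Atoh7 and Fn1 cluster as bushy, and leaving out clusters with molecular layer or Purkinje markers. Work was done in Python 3.11.15 and R 4.3.3.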

Results

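The series measured gene expression in the mouse cochlear nucleus, the brainstem station where auditory nerve fibres hand sound information to several parallel pathways. Its title asks which molecular features set apart the cells that start those pathways. The labels list 11 single-nucleus libraries and 387 patch-seq cells, neurons whose cytoplasm was drawn into a recording pipette for RNA sequencing. UMI count matrices of 9 of the libraries were analysed, under the names the labels give them. Their total UMI counts were 53247499 in p1s1, 44663958 in p3s1, 43833028 in p3s2, 23129456 in p4s1, 18887956 in p5s1, 37601430 in p5s2, 50255036 in p6s1, 49680350 in p6s2 and 92951524 in p7s1. Of 78685 barcodes, 70354 nuclei were used after filters and doublet removal. Patch-seq cells had a median of 2965654 counted reads (549448 to 13112026) and 7931 detected genes.

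Marker genes named most nuclei as granule-like neurons, with a mean share of 38.4% ± 15.5 (SD, n = 9 libraries), and as oligodendrocyte-like cells, with 17.1% ± 3.96. The projection neurons of the ventral nucleus were rare. Bushy-like nuclei made up 1.87% ± 1.06, T-stellate-like nuclei 1.45% ± 0.890 and octopus-like nuclei 0.158% ± 0.125 (SD, n = 9). Unipolar brush-like nuclei, excitatory interneurons of the granule cell domain, made up 4.28% ± 1.75, cartwheel-like nuclei of the dorsal nucleus 0.809% ± 0.540 and Golgi-like nuclei 0.393% ± 0.187. Nuclei with markers of cerebellar molecular layer interneurons made up 0.818% ± 0.767, with 2.32% in p3s1 and 1.83% in p3s2 against 0.194% to 0.889% in the others. Inhibitory nuclei given no type made up 3.01% ± 1.36 and glutamatergic nuclei given no type 2.11% ± 1.14. The labels give no groups of libraries, so shares were described and not tested. Libraries p3s1 and p3s2 held 62.4% and 62.8% granule-like nuclei, against 21.4% to 39.8% in the others. They held 0 and 2 octopus-like nuclei, against 3 to 48 in the others.

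**Figure D1:**
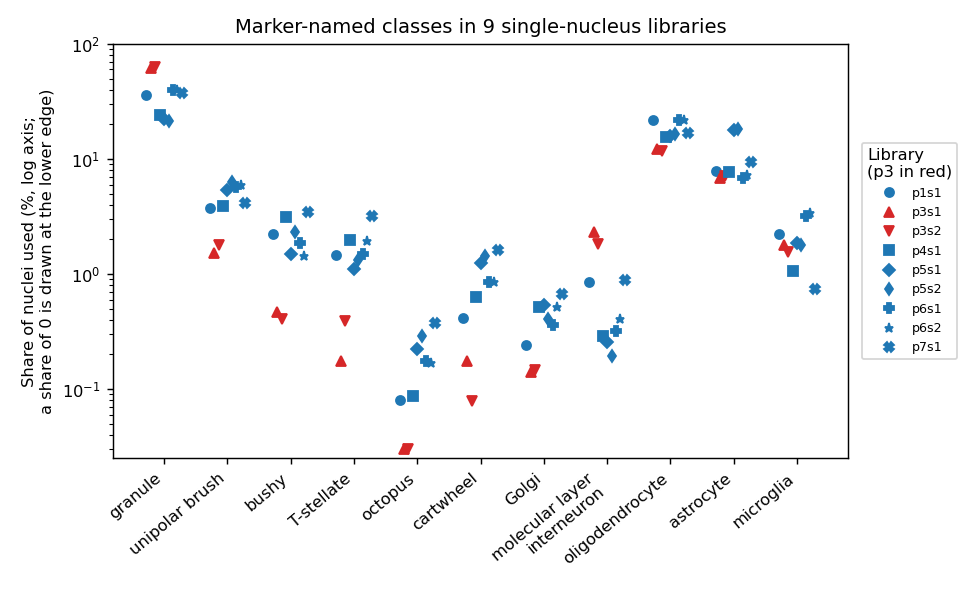
Share of nuclei (percent, log axis) of 11 marker-named classes in each of 9 libraries. Each point is 1 library, those of p3 in red, and a share of 0 is drawn near the lower edge. The p3 libraries held 62.4% and 62.8% granule-like nuclei and the lowest shares of bushy-like and cartwheel-like nuclei.

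Bushy-like and T-stellate-like nuclei, relay types that receive the same auditory nerve input, were compared to ask which channel, receptor and wiring genes separate them. T-stellate-like nuclei carried far more transcript of several inhibitory receptor genes. Gabrb1 (ENSMUSG00000029212, GRCm38 chromosome 5, 71658113 to 72149037), a GABA-A receptor beta subunit, stood at 228 ± 44.96 CPM (counts scaled to the TMM-adjusted total of the class in a library, mean ± SD, n = 9 libraries) in T-stellate-like and 10.8 ± 7.91 in bushy-like nuclei. Its log2 fold change, bushy-like over T-stellate-like here and for every gene of this comparison, was -4.45 ± 0.15 (SE). Glra3, a glycine receptor alpha subunit, had a log2 fold change of -6.25 ± 0.23, while Glra4, another, was higher in bushy-like nuclei at 2.52 ± 0.15. Bushy-like nuclei were higher in Kcna1 (1.13 ± 0.06), which encodes the Kv1.1 subunit of low-threshold potassium channels, and in Kcnab3 (2.96 ± 0.21), a Kv1 beta subunit. Semaphorin Sema3e (ENSMUSG00000063531; chromosome 5, 14025276 to 14256689) was higher in bushy-like nuclei by 4.05 ± 0.15 and the ephrin receptor gene Epha3 lower, at -3.52 ± 0.17.

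Of 5491 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 490 were called, 31.6% of them higher in bushy-like and the rest in T-stellate-like nuclei, over 1306 and 1079 nuclei. The genes named here moved the same way in all 9 libraries, with adjusted p = 4.52e-08 or less (the highest in Grin3a). Among 15 measured GABA receptor genes, 5 were lower and 1 higher in bushy-like nuclei and 9 were not called (camera adjusted p = 0.00025, and adjusted p = 0.0322 with an estimated correlation). Of 10 genes of the leak and inward rectifier list, 4 were lower, such as Kcnk10 at -1.67 ± 0.06 and Kcnj6 at -1.61 ± 0.14, and 1 was higher (adjusted p = 0.000501, and adjusted p = 0.114 with an estimated correlation). Of 4 neurofilament genes, which build the axonal cytoskeleton, 3 were higher, including Nefl at 1.83 ± 0.13 and Nefh at 1.58 ± 0.13 (adjusted p = 0.000415, and adjusted p = 0.121 with an estimated correlation). Of 25 vesicle release genes, 6 were lower, led by the priming factor Unc13c at -3.64 ± 0.13, and 1 was higher (adjusted p = 0.00619, and adjusted p = 0.114 with an estimated correlation). The 9 Kv1 channel genes held 2 higher members and none lower (adjusted p = 0.0115, and adjusted p = 0.114 with an estimated correlation). The 14 NMDA, kainate and delta receptor genes held 6 lower and 2 higher, Grin3a at -1.99 ± 0.22 and Grik3 at 1.98 ± 0.21 (adjusted p = 0.0115, and adjusted p = 0.114 with an estimated correlation).

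Other listed genes moved without their list being called by camera. Sodium channel partners of the fibroblast growth factor family went apart, Fgf13 at -3.54 ± 0.13 and Fgf11 at 2.41 ± 0.23. Channel genes of other lists included Kcnc2 (Kv3.2) at -4.16 ± 0.28, the calcium channel gene Cacna1e at -3.98 ± 0.14, Kcnh7 of the EAG family at -1.91 ± 0.06 and Hcn4 at 1.12 ± 0.12. Acan, which encodes aggrecan of perineuronal nets, was higher in bushy-like nuclei at 2.36 ± 0.15. The metabotropic glutamate receptor gene Grm8 was lower at -4.09 ± 0.15 and the AMPA receptor auxiliary gene Shisa9 at -4.31 ± 0.28. Outside the lists, Zmat4 (4.44 ± 0.17) and Klhl1 (3.77 ± 0.12) led in bushy-like nuclei, and Tmem132d (-7.13 ± 0.20) and Tmem200a (-5.41 ± 0.21) in T-stellate-like nuclei. Counts adjusted over the list alone equalled the counts over all genes tested in every list. Median, mean and camera direction differed in sign in 3 lists, those of calcium- and sodium-activated potassium, Kv7 and EAG family, and sodium channels. Granule markers (Gabra6, Fat2 and Cbln3 summed) stood at 63.99 ± 53.96 CPM in T-stellate-like and 23.95 ± 23.5 in bushy-like nuclei, higher in bushy-like nuclei in 1 of 9 libraries. Counting a separate cluster of 675 nuclei with the markers Atoh7 and Fn1 as bushy, an alternative chosen after seeing the data, ended the calls of Kcnh8 (-2.77 to -0.45), Kcnj6 (-0.51), Grin3a (-0.41), Lrrtm3 (-0.92) and Syt9 (-0.78). Of the 490 calls, 74.5% were shared under that alternative and 1 gene was called the other way. With nuclei thinned to 1000 UMIs, Kcnma1 moved from -1.05 to -0.97, under the threshold of 1.

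**Figure D2:**
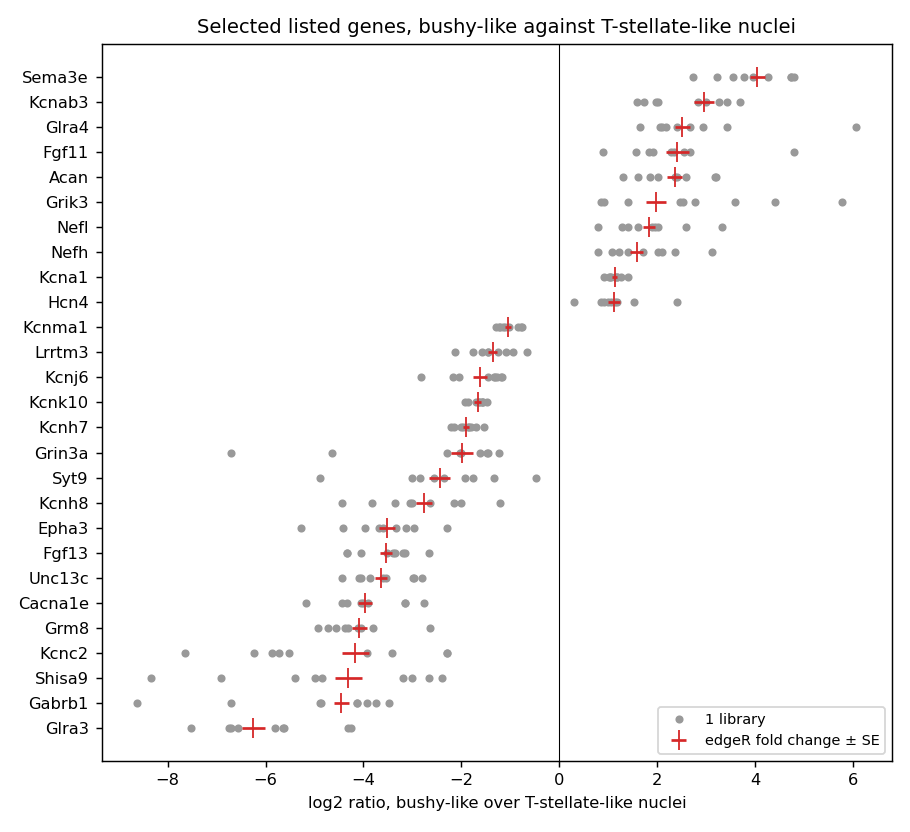
Log2 ratio of bushy-like over T-stellate-like nuclei for a selection of the listed genes called in that comparison. Grey points are the 9 libraries, with 0.5 CPM added to each class, and red marks the edgeR log2 fold change ± SE, from -6.25 for Glra3 to 4.05 for Sema3e.

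Octopus-like and bushy-like nuclei, both known as detectors of coincident input, were compared in the 4 libraries with at least 10 nuclei of each, p5s2, p6s1, p6s2 and p7s1. Acan (ENSMUSG00000030607; chromosome 7, 79053483 to 79115099), the aggrecan gene of perineuronal nets, stood at 90.1 ± 17.5 CPM in octopus-like and 30.9 ± 5.01 in bushy-like nuclei (SD, n = 4), a log2 fold change, octopus-like over bushy-like, of 1.53 ± 0.17 (SE). Tnr, also of perineuronal nets, was higher at 1.51 ± 0.11, as was Kcna2 (Kv1.2, at 1.09 ± 0.14). The AMPA receptor gene Gria1 (1.93 ± 0.28) and the auxiliary gene Cacng5 (3.11 ± 0.24) were higher too. The pacemaker channel gene Hcn4 was lower in octopus-like nuclei at -1.47 ± 0.29. Also lower were Kcns3 (-4.14 ± 0.34), a modifier of Kv2 channels, and Kcnh5 (-2.61 ± 0.14). Glra4 gave no count in octopus-like nuclei and was at least 20.6-fold lower there, with the floor of 3 counts taken over the group.

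Of 5163 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 457 were called, 51.2% of them higher in octopus-like and the rest in bushy-like nuclei, over 99 and 907 nuclei. Named genes moved the same way in all 4 libraries, with adjusted p = 0.00275 or less (the highest in Glra2). Of 11 calcium channel genes, 2 were higher and none lower in octopus-like nuclei, Cacna1e at 2.60 ± 0.30 and Cacna2d1 at 1.36 ± 0.11 (camera adjusted p = 0.0339, and adjusted p = 0.344 with an estimated correlation). Of 14 NMDA, kainate and delta receptor genes, 4 were higher and 2 lower, with Grin3a at 1.98 ± 0.40 and Grik4 at -2.30 ± 0.27 (adjusted p = 0.0384, and adjusted p = 0.344 with an estimated correlation). The 25 vesicle release genes held 4 higher and 2 lower, led by Rims3 at 3.75 ± 0.33 and Cadps2 at 3.47 ± 0.23, and the list was not called (adjusted p = 0.0868). The 12 sodium channel genes held 1 called member, Fgf11, which gave no count in octopus-like nuclei and was at least 7.49-fold lower. With Fgf11 at that bound the list's median log2 fold change was -0.22. Of 11 genes of the AMPA receptor list 2 were higher and 1 lower (adjusted p = 0.0521), of 5 perineuronal net genes 2 were higher and 1 lower (adjusted p = 0.0983), and of 4 genes of the HCN channel list 1 was higher and 1 lower (adjusted p = 0.0817), and none of these 3 lists was called. Of 9 genes of the metabotropic glutamate receptor list 3 were higher and 3 lower, with Grm5 at 1.86 ± 0.11 and the partner gene Homer1 at -1.77 ± 0.13. Counts adjusted over the list alone equalled these in every list. Signs of median, mean and test differed in 5 lists, among them axon guidance and Kv4 channels.

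The transcription factor gene Barhl2 (ENSMUSG00000034384; chromosome 5, 106452523 to 106458166) gave 40 counts in octopus-like and none in bushy-like nuclei, at least 84.8-fold higher, and Mat1a was at least 42.4-fold higher on the same floor. Glp2r, with 1 count in bushy-like nuclei, was 184.5 times as high in octopus-like nuclei (95% counting interval 30.6 to 7537). Tmem132c (5.89 ± 0.16) and the RNA on its other strand, Tmem132cos (6.23 ± 0.18), were also higher, the labels not saying whether counting was stranded. Tox, with 2 counts in octopus-like nuclei, was 76.2 times as high in bushy-like nuclei (95% counting interval 21.04 to 630.3), and Trpc5 was lower in octopus-like nuclei at -4.83 ± 0.18. Granule markers stood at 41.9 ± 33.5 CPM in octopus-like and 12.7 ± 8.0 in bushy-like nuclei, higher in 3 of 4 libraries. Kcna2 went under the threshold of 1 without p6s1 (0.99) and with no filter on low counts (0.997), Nalcn (-1.32) without p7s1 (-0.93) and with nuclei thinned to 1000 UMIs (-0.42), and Kcnk10 (-1.24) without p7s1 (-0.79). Counting the Atoh7 and Fn1 cluster as bushy ended the calls of Epha3 (0.51), Cacna1e (0.45), Cacna2d1 (0.56), Glra2 (0.40), Grm5 (0.81), Grin3a (0.53) and Cadps2 (0.76) and turned Kcnh8 from 2.14 to -0.38 (adjusted p = 0.483 by edgeR). Of the 457 calls, 75.5% were shared under that alternative.

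Octopus-like nuclei were set against T-stellate-like nuclei, a tonically firing type, in the same 4 libraries. Octopus-like nuclei held more Kcna1 (log2 fold change, octopus-like over T-stellate-like, 1.76 ± 0.11 (SE), n = 4) and Kcna2 (1.90 ± 0.16). Kcnc2 (ENSMUSG00000035681; chromosome 10, 112271121 to 112467024), which encodes Kv3.2, gave 1791 counts in T-stellate-like and none in octopus-like nuclei, at least 84.4-fold lower with the floor of 3 counts over the group. Of 15 GABA receptor genes 6 were lower in octopus-like nuclei, of 5 glycine receptor genes 2 were lower, and the others were not called. Glra1 stood at 42.8 ± 11.9 CPM against 313.9 ± 52.2 (SD; log2 fold change -3.00 ± 0.17), Gabra4 was at least 12.8-fold lower, and Gabra2, with 3 counts, was 58.5 times as high in T-stellate-like nuclei (95% counting interval 19.97 to 284).

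Of 5057 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 619 were called, 39.4% of them higher in octopus-like and the rest in T-stellate-like nuclei, over 99 and 816 nuclei. Named genes moved the same way in all 4 libraries, with adjusted p = 0.00167 or less (the highest in Cbln1). Camera called 7 of 19 lists, none of them with an estimated correlation, each at adjusted p = 0.26 with an estimated correlation. The lists of GABA receptors (adjusted p = 1.04e-07) and glycine receptors (adjusted p = 0.0441) were called lower, the glycine list with a median log2 fold change of -0.10. With Gabra4 at its bound the GABA list's median log2 fold change was -0.78. Of 4 neurofilament genes 3 were higher, including Nefl at 1.63 ± 0.15 and Nefm at 1.24 ± 0.12 (adjusted p = 0.00127). The 8 Kv1 genes held 2 higher and 1 lower (adjusted p = 0.00314), and the 6 Kv2 and Kv3 genes 1 higher and 4 lower, with a median of -2.63 when Kcnc2 stood at its bound (adjusted p = 0.00314). Of 9 Kv7 and EAG family genes 5 were lower and 2 higher, with Kcnh1 at -3.05 ± 0.27 (adjusted p = 0.00784). Of 9 leak and inward rectifier genes 2 were lower, Kcnk10 at -2.86 ± 0.22 and Nalcn at -2.28 ± 0.19 (adjusted p = 0.012).

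Other genes included Acan (3.89 ± 0.24), the kainate receptor genes Grik3 (3.08 ± 0.28) and Grik4 (-4.11 ± 0.25), Fgf13 (-3.47 ± 0.14), Shisa6 (-3.87 ± 0.17) and the guidance pair Robo1 (3.42 ± 0.11) and Slit2 (-3.89 ± 0.22), a receptor and its ligand. Barhl2, with 2 counts in T-stellate-like nuclei, was 141.4 times as high in octopus-like nuclei (95% counting interval 36.7 to 1208), and Dkk3 was higher at 6.47 ± 0.35. Colq and Insrr gave no count in octopus-like nuclei and were at least 18.4-fold and 13.7-fold lower. Counts adjusted over the list alone equalled those over all genes tested in every list, and signs of median, mean and test differed in the AMPA receptor, calcium channel and sodium channel lists. Cacna2d3 (1.04 ± 0.11) lost its call without p5s2 (0.93), with no filter on low counts (0.92) and with nuclei thinned to 1000 UMIs (0.84).

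Unipolar brush-like nuclei were compared with granule-like nuclei, the other glutamatergic interneurons of the granule cell domain, in all 9 libraries. The metabotropic glutamate receptor gene Grm8 (ENSMUSG00000024211; chromosome 6, 27275119 to 28135178) stood at 2302 ± 249 CPM in unipolar brush-like and 6.88 ± 2.61 in granule-like nuclei (SD, n = 9), a log2 fold change, unipolar brush-like over granule-like, of 8.45 ± 0.15 (SE). Lower genes included the NMDA receptor gene Grin2a at -5.81 ± 0.17, the kainate receptor gene Grik2 at -3.80 ± 0.16 and Gabrb2 at -3.87 ± 0.11. AMPA receptor genes went both ways, with Gria4 at -4.15 ± 0.12 and the auxiliary gene Gsg1l at 5.38 ± 0.13. Of 11 genes of the AMPA receptor list 3 were higher and 3 lower, and the list was not called (adjusted p = 0.807 by camera). The neuropeptide gene Adcyap1, which encodes PACAP, was higher at 5.21 ± 0.22.

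Of 6159 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 768 were called, 54.2% of them higher in unipolar brush-like and the rest in granule-like nuclei, over 2929 and 29307 nuclei. Named genes moved the same way in all 9 libraries, with adjusted p = 1.54e-05 or less (the highest in Glra2). Of 28 vesicle release genes 9 were lower and 1 higher, with Syt6 at -5.81 ± 0.20 and Cadps2 at -4.60 ± 0.12 (camera adjusted p = 8.9e-05, and adjusted p = 0.0216 with an estimated correlation). Of 13 GABA receptor genes 8 were lower and 1 higher (adjusted p = 9.93e-06, and adjusted p = 0.0889 with an estimated correlation). Of 5 genes of the HCN channel list 3 were higher, including Hcn3 at 2.22 ± 0.15 (adjusted p = 0.000988, and adjusted p = 0.115 with an estimated correlation). The 13 NMDA, kainate and delta receptor genes held 6 lower and 1 higher (adjusted p = 0.00148, and adjusted p = 0.135 with an estimated correlation). Of 24 synaptic adhesion genes 8 were lower (adjusted p = 0.00166, and adjusted p = 0.0785 with an estimated correlation). Of 9 Kv1 genes 2 were lower, the Kv1 partner Lgi1 at -3.11 ± 0.09 and Kcnab1 at -2.57 ± 0.09 (adjusted p = 0.00409, and adjusted p = 0.115 with an estimated correlation). Of 7 genes of the Kv4 list 2 were lower, Kcnip4 at -2.98 ± 0.09 and Kcnd3 at -2.65 ± 0.09, and 1 was higher (adjusted p = 0.00865, and adjusted p = 0.115 with an estimated correlation). Of 10 genes of the metabotropic glutamate receptor list 4 were higher and 1 lower (adjusted p = 0.0114, and adjusted p = 0.115 with an estimated correlation). Of 31 axon guidance genes 12 were higher and 6 lower, with Sema3d at 5.27 ± 0.18 and Unc5d at 5.25 ± 0.21 (adjusted p = 0.0325, and adjusted p = 0.335 with an estimated correlation).

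Of 11 immediate early genes 2 were lower and 1 higher (adjusted p = 0.154 by camera), and of 4 neuropeptide genes 1 was higher and 1 lower (adjusted p = 0.631). Outside the lists, Sntg2 (8.09 ± 0.10) and Adcy2 (7.38 ± 0.19) led in unipolar brush-like nuclei, and Rbfox1 (-6.13 ± 0.28), a splicing factor gene, and Col27a1 (-5.87 ± 0.14) in granule-like nuclei. Counts adjusted over the list alone equalled those over all genes tested, and signs of median, mean and test differed in the AMPA receptor, calcium channel, Kv7 and EAG family, and perineuronal net lists. Granule markers stood at 171.5 ± 34.1 CPM in unipolar brush-like nuclei, against 1001 ± 276 in granule-like nuclei. Astrocyte markers stood at 41.3 ± 17.9 and 54.1 ± 24.8 CPM, lower in unipolar brush-like nuclei in all 9 libraries, and oligodendrocyte markers were lower in 7 of 9. In the p3 libraries 97.6% and 98.1% of granule-like nuclei lay in 3 clusters that held 0.907% to 13.1% of them elsewhere. Without these libraries, an alternative chosen after seeing the data, 808 genes were called, and Glra2 (1.08 to 0.83) went under the threshold of 1. Glra2 also did so without p3s1 (0.96), without p3s2 (0.95), with no low-count filter (0.99) and without library as a replicate block (0.99).

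Unipolar brush-like nuclei formed 2 clusters, of 1831 and 1098 nuclei, described here by genes chosen after their values were seen. The smaller cluster held more Calb2 (540 ± 312.1 CPM against 46.8 ± 21.7, SD, n = 9) and more Plcb1 (1078 ± 163.4 against 218.1 ± 32.2), genes that took part in the clustering. Both differences pointed the same way in 9 of 9 libraries, and neither was tested.

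Inhibitory nuclei of every type were compared with bushy-like, T-stellate-like and octopus-like nuclei pooled as projection nuclei, in 9 libraries. The inhibitory pool of 3646 nuclei held 2146 nuclei given no type, 573 cartwheel-like and 274 Golgi-like nuclei. The pool also held 653 nuclei with molecular layer interneuron markers, 213 of these in p3s1. Inhibitory nuclei held more of several glutamate receptor genes. The AMPA receptor gene Gria1 (ENSMUSG00000020524; chromosome 11, 57011387 to 57330244) stood at 261.7 ± 94.5 CPM in inhibitory and 10.1 ± 3.27 in projection nuclei (SD, n = 9), a log2 fold change, inhibitory over projection, of 4.69 ± 0.14 (SE). The NMDA receptor gene Grin2b (3.08 ± 0.12) and the T-type calcium channel gene Cacna1g (5.04 ± 0.18) were also higher. Projection nuclei held more Hcn4 (-1.88 ± 0.16), Nefm (-1.69 ± 0.13) and the transcription factor genes Ebf3 (-4.61 ± 0.23) and Ebf1 (-4.55 ± 0.37).

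Of 6713 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 863 were called, 51.3% of them higher in inhibitory and the rest in projection nuclei, over 3646 and 2502 nuclei. Named genes moved the same way in all 9 libraries, with adjusted p = 4.89e-06 or less (the highest in Nefh). Of 10 Kv7 and EAG family genes 5 were lower in inhibitory nuclei and 1 was higher (camera adjusted p = 0.00535, and adjusted p = 0.135 with an estimated correlation). Of 15 NMDA, kainate and delta receptor genes 6 were higher and 1 lower (adjusted p = 0.00535, and adjusted p = 0.135 with an estimated correlation). Of 15 genes of the AMPA receptor list 6 were higher and 2 lower (adjusted p = 0.0206, and adjusted p = 0.27 with an estimated correlation), and of 14 calcium channel genes 3 were higher (adjusted p = 0.0206, and adjusted p = 0.135 with an estimated correlation). Of 4 neurofilament genes 3 were lower (adjusted p = 0.0166, and adjusted p = 0.364 with an estimated correlation). Of 3 measured Hox genes 1 was higher, Hoxa3 at 3.33 ± 0.19, and the list was not called (adjusted p = 0.57). Outside the lists, Nrk, with 2 counts in projection nuclei, was 444.8 times as high in inhibitory nuclei (95% counting interval 122.8 to 3679). Stac (7.62 ± 0.19) and Ryr1 (7.11 ± 0.12), both tied to calcium release or channel trafficking in muscle, and Prkcd (6.08 ± 0.15) were also higher in inhibitory nuclei. The levels of Stac and Ryr1 lay mostly in cartwheel-like nuclei, where Stac stood at 1764 ± 101.96 CPM against 15.1 ± 15.7 in other inhibitory nuclei and Ryr1 at 493.75 ± 66.2 against 8.25 ± 9.73 (SD, n = 8). Without clusters with molecular layer or Purkinje markers, an alternative chosen after seeing the data, 833 genes were called. Counts adjusted over the list alone equalled these, and signs of median, mean and test differed in the GABA receptor, Kv2 and Kv3, perineuronal net and synaptic adhesion lists. Oligodendrocyte markers stood at 339.1 ± 177.1 CPM in inhibitory and 243.2 ± 145.1 in projection nuclei, and microglia markers at 113.8 ± 48.6 and 99.4 ± 44.5, both higher in inhibitory nuclei in 9 of 9 libraries.

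Cartwheel-like nuclei, inhibitory neurons of the dorsal nucleus, were compared with all other inhibitory nuclei in the 8 libraries with at least 10 of each, all but p3s2. Kcnq5 and Kcnq3, which encode subunits of Kv7 channels, carriers of the M-current, were lower in cartwheel-like nuclei. Kcnq5 (ENSMUSG00000028033; chromosome 1, 21398403 to 21961942) stood at 4.01 ± 4.08 CPM in cartwheel-like and 568 ± 78.6 in other inhibitory nuclei (SD, n = 8), a log2 fold change, cartwheel-like over other, of -7.01 ± 0.23 (SE), and Kcnq3 at -5.09 ± 0.28. The NMDA receptor gene Grin2a (-5.22 ± 0.26) and the metabotropic receptor genes Grm5 (-4.79 ± 0.32) and Grm8 (-5.03 ± 0.23) were lower too. Cartwheel-like nuclei held more Stac (7.05 ± 0.32), Ryr1 (6.01 ± 0.33), Cacna2d1 (4.62 ± 0.12), Gabrg1 (4.78 ± 0.15) and Kcnab1 (2.69 ± 0.10). The perineuronal net gene Tnr was higher at 3.04 ± 0.07.

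Of 5386 genes tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 958 were called, 43.2% of them higher in cartwheel-like and the rest in other inhibitory nuclei, over 566 and 2814 nuclei. Named genes moved the same way in all 8 libraries, with adjusted p = 9.12e-07 or less (the highest in Kcnc4). Without clusters with molecular layer or Purkinje markers 895 genes were called. Of 7 Kv7 and EAG family genes 5 were lower and none higher (camera adjusted p = 0.00196, and adjusted p = 0.129 with an estimated correlation). Of 25 vesicle release genes 7 were lower and 2 higher, with Sv2b at -4.08 ± 0.23 and Rph3a at -3.24 ± 0.15 (adjusted p = 0.00785, and adjusted p = 0.129 with an estimated correlation). Of 31 axon guidance genes 19 were lower and 5 higher, with Epha6 at -4.91 ± 0.24 and Nrp1 at -4.39 ± 0.22 (adjusted p = 0.0113, and adjusted p = 0.129 with an estimated correlation). Of 14 NMDA, kainate and delta receptor genes 9 were lower and 2 higher (adjusted p = 0.0113, and adjusted p = 0.129 with an estimated correlation). All 7 genes of the Kv4 list were called, 5 lower and 2 higher, with Kcnd2 at -2.69 ± 0.18 (adjusted p = 0.0689), and of 5 genes of the calcium- and sodium-activated potassium channel list 3 were lower, Kcnt2 among them at -6.23 ± 0.27, and 1 higher (adjusted p = 0.0689). Of 5 perineuronal net genes 1 was higher and 2 lower (adjusted p = 0.806), and of 13 sodium channel genes 2 were higher and 4 lower (adjusted p = 0.105).

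The AMPA receptor auxiliary gene Cacng3 gave no count in cartwheel-like nuclei and was at least 62.02-fold lower, with the floor of 3 counts over the group, and with it at that bound the AMPA receptor list's median log2 fold change was 0.30. The serotonin receptor gene Htr4 was at least 101-fold lower and Nxf7 at least 208.9-fold higher on the same floor. Counts adjusted over the list alone equalled those over all genes tested in every list, and signs of median, mean and test differed in 5 lists, those of AMPA receptors, calcium channels, glycine receptors, Kv2 and Kv3 channels, and perineuronal nets. Oligodendrocyte markers stood at 213 ± 117.7 CPM in cartwheel-like and 342.4 ± 180.9 in other inhibitory nuclei, lower in all 8 libraries. Granule markers stood at 15.2 ± 10.0 and 52.4 ± 13.6 CPM, also lower in all 8, and astrocyte and microglia markers were lower in 7 of 8. Of the genes named by the rule across the comparisons, 7 overlap another coding gene on the same strand, among them Grin3a, Cadps2, Hoxa3 and Kcnip1, and 25 overlap one on the other strand.

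The 387 patch-seq cells were assigned to the neuron or glial class whose single-nucleus profile they matched best by rank correlation, as a second kind of cell in which to look for the same genes. The labels name no animal for any cell, so the cells stand as 1 sample and no test was made. With all clustering genes, 210 cells (54.3%, exact 95% binomial interval 49.2% to 59.3%) matched bushy-like and 12 (3.10%, 1.61% to 5.35%) cartwheel-like profiles, and 1 each T-stellate-like and octopus-like. A further 53 cells (13.7%, 10.4% to 17.5%) matched the molecular layer interneuron class and 88 (22.7%, 18.7% to 27.2%) glutamatergic clusters with no type, 71 of them 1 cluster. The astrocyte profile was matched by 1 cell and the microglia profile by 2. The median gap in correlation to the next class was 0.0111. With the fixed markers and 300 variable genes, the other assignment set in advance, 30.7% of cells (26.2% to 35.6%) matched bushy-like, 45 (11.6%, 8.61% to 15.2%) T-stellate-like and 40 (10.3%, 7.49% to 13.8%) octopus-like profiles. The molecular layer interneuron class then held 4 cells (1.03%, 0.282% to 2.63%), and the cluster that had held 71 cells held 1. A further assignment with each gene centred, chosen after seeing the data, gave 89, 32 and 37 cells for these classes.

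With markers and 300 genes, Kcnc2 stood at 85.7 RPM (reads scaled to the total of the class) in T-stellate-like cells (exact Poisson 95% interval 84.3 to 87.1), 0.446 in bushy-like cells (0.385 to 0.515) and 0.356 in octopus-like cells (0.271 to 0.459). These intervals treat reads as independent and leave out the spread between cells. Kcnab3 stood at 108.6 (107.6 to 109.6) in bushy-like and 3.73 (3.45 to 4.02) in T-stellate-like cells, and Acan at 65.8 (64.6 to 67.045) in octopus-like and 2.85 (2.60 to 3.11) in T-stellate-like cells. Of the genes called in nuclei that had reads, 94.5% pointed the same way in cells for bushy-like over T-stellate-like, 88.97% for octopus-like over bushy-like and 93.3% for octopus-like over T-stellate-like. For inhibitory over projection cells 92.4% did so, and for cartwheel-like over other inhibitory cells 93.1%. Of the named genes with reads, 33 of 38 pointed the same way for octopus-like over bushy-like. Among the exceptions Gria1, higher in octopus-like than in bushy-like nuclei, was lower in cells, at 9.24 (8.79 to 9.72) against 12.5 (12.2 to 12.8) RPM. No spread between cells was taken, so whether this Gria1 difference exceeds it cannot be told. The assignment drew on other genes than those called, and genes are not independent replicates. It did match cells to these same nuclei profiles, so agreement in direction was partly built in and is no independent test. No share over all genes tested was taken for comparison. With all clustering genes, 1 T-stellate-like and 1 octopus-like cell were too few for the comparisons among bushy-like, T-stellate-like and octopus-like cells.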

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

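Of the tests below, those of genes above both classes, of UMIs in both clusters weighed for doublets, and of splits that keep p codes whole, the value over genes at least 4-fold higher in p3, and the use of a spread for the share of bushy-like genes were chosen only after the result was seen.

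Granule-like nuclei of p3s1 and p3s2 fell into other clusters than those of the other libraries, with 97.6% and 98.1% in 3 clusters against 0.907% to 13.1% elsewhere. Cerebellar tissue in these libraries would lower the Hox genes of the brainstem, and their mean was 0.617 of that in the other libraries, between the bounds set, while En2, a cerebellar gene, stood at 50.96 and 51.5 CPM against 1.08 to 9.72. Nuclei with markers of cerebellar molecular layer interneurons made up 1.83% and 2.32% of the p3 libraries against 0.194% to 0.889% of the others. Free RNA may account for part, since genes higher in p3 granule-like nuclei stood in oligodendrocyte-like nuclei at a median of 0.599 of their granule level, though at 0.089 over the 27 genes at least 4-fold higher. Each gene was scaled within its library before clustering, and p3 held 62.4% and 62.8% granule-like nuclei against 21.4% to 39.8% elsewhere. Whether this scaling moved the p3 granule-like nuclei to other clusters was not tested. The median mitochondrial percent was 0.724 and 0.714 in p3, 0.637 in p1s1 and 0.0242 to 0.178 in the others, and its part was not tested either. Cerebellar tissue stays open, and no biological explanation was tested, as the labels give no group that sets p3 apart.

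A cluster of 675 nuclei carried both Atoh7 and Fn1, markers fixed for bushy and T-stellate neurons. The tables argue against doublets of bushy and T-stellate nuclei as the source of the whole cluster. Doublets would carry more UMIs, and the median UMI was 0.984 of that of bushy-like and T-stellate-like nuclei (median over 9 libraries, 0.845 to 1.11). A doublet cannot exceed both of its sources, and 2 genes kept out of the clustering, Npffr2 and Cpne4, stood at 4-fold or more of both classes in every library, a number between the bounds set. Cpne4 stood at 664.5 ± 168.1 CPM in the cluster, 66.5 ± 17.1 in bushy-like and 31.8 ± 13.4 in T-stellate-like nuclei (SD, n = 9). Genes at least 4-fold higher in T-stellate-like nuclei stood at a median log2 ratio of -1.86 to those nuclei, between the bounds set, and a smaller share of doublets was not tested. A kind of bushy nucleus stays open. It would put at least 75% of called genes nearer the bushy-like mean, and 58.98% lay there, with libraries from 47.8% to 63.1% (SD 4.6), so that the bound of 60% lay within the spread. The design gives no biological explanation.

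A cluster of 448 nuclei carried Slc17a6, a glutamate transporter gene, and inhibitory markers. Nuclei with UMIs of both were 0.437 of the number independence gives (48.4% with Slc17a6, 46.4% with an inhibitory marker, 9.82% with both), which is consistent with 2 kinds of nuclei in 1 cluster. The same ratio was 1.08 in bushy-like and 1.05 in T-stellate-like nuclei. Doublets of glutamatergic and inhibitory nuclei would carry more UMIs, and the median UMI was 0.911 of that of such nuclei, which argues against doublets. No biological explanation was tested.

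Swapping the classes within libraries gave other splits of the same sums. In 4 comparisons 1 split, the real one, gave as many genes. These were bushy-like over T-stellate-like (490 genes, 0 in the highest other of 100 splits) and unipolar brush-like over granule-like (768, with 68.2% of that number in the highest other). The others were inhibitory over projection (863, highest other 684) and cartwheel-like over other inhibitory nuclei (958, highest other 693). The classes were clusters of these same nuclei, so a real split above the swapped ones was largely built in. The splits therefore cannot tell whether chance shaped the classes, and no conclusion on chance is drawn from them. For octopus-like over bushy-like (457, highest other 0) and over T-stellate-like nuclei (619, highest other 0) the 8 splits are too few for a share under 0.05. Libraries of one p code resemble each other and may be technical replicates, so the splits were repeated with the libraries of a p code swapped at once, which leaves 32 splits of 6 p codes in the first 4 comparisons named. The real split alone gave as many genes in each of them, and the highest other split gave 68.8%, 81.8%, 79.3% and 79.02% of the real number, in the order above. For the octopus-like comparisons 4 splits are too few, with 0 genes in the highest other.

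A library far from the others was found in 14 groups of library values, 6.70% of those examined, where chance gives about 1 in 20. Total UMIs were 92951524 in p7s1 against 18887956 to 53247499 elsewhere, and the share of the cluster with both transmitters was 2.05% in p7s1 against 0.164% to 0.870%. The others were log2 ratios of named genes, with 0.5 CPM added to each class, given with the range of the other libraries. A library with no count of a class gives only a bound, so 87 ratios with such a library were left out, a choice made after 11 of them had stood apart. For bushy-like over T-stellate-like nuclei, Grm8 stood at -2.64 in p6s1 (-4.94 to -3.80). For octopus-like over T-stellate-like nuclei, Nefl stood at 1.38 in p6s1 (1.66 to 1.67), Cbln1 at -2.51 in p7s1 (-1.91 to -1.83) and Zfp804b at 6.92 in p7s1 (4.61 to 4.93). For unipolar brush-like over granule-like nuclei, Kcnt2 stood at 4.02 in p3s1 (2.41 to 3.23) and Kcnh8 at 4.02 in p3s2 (2.49 to 3.06). For inhibitory over projection nuclei, Syt9 stood at 4.23 in p3s2 (1.22 to 2.74) and Prkcd at 7.04 in p7s1 (5.15 to 6.07). For cartwheel-like over other inhibitory nuclei, p3s1 stood apart in Cacna2d1 at 5.69 (4.10 to 4.8) and Fgf11 at 0.94 (2.79 to 4.26), p1s1 in Grin2a at -2.84 (-6.32 to -5.19) and p5s1 in Tnr at 3.29 (2.84 to 3.05).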

How the results depend on the processing

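The alternatives without p3, with the Atoh7 and Fn1 cluster as bushy, without molecular layer or Purkinje clusters and with centred genes were chosen after seeing the data. Of 4827 values of named genes under alternatives, 4798 kept their call, 28 lost it and 1 reversed. The reversed value was Kcnh8 in octopus-like over bushy-like nuclei at -0.38 with that cluster as bushy (the cause was not tested). Named genes were chosen as called and alike in direction in every library, so kept calls were partly built in. This holds most for the 1939 values with 1 library left out. Genes an alternative could not test were not counted. The 4798 are thus no measure of all calls. Of all calls, 21.2%, 21.2%, 19.2%, 56.1%, 31.5% and 25.3% were shared under thinning to 1000 UMIs, in the order of the report. Most others were not among the genes tested there. Counts of called genes are given as a percent of genes tested, but were judged as counts, with a change of over 1.5 times taken as a move. They were 8.92%, 8.85%, 12.2%, 12.5%, 12.9% and 17.8% in the 6 comparisons, in the order of the report. With no filter on low counts more genes were tested, and the counts moved up to 1011 (8.19%), 1410 (10.9%), 1519 (11.7%) and 1892 (15.4%) in the bushy-like over T-stellate-like, unipolar brush-like, inhibitory and cartwheel-like comparisons. Thinning to 1000 UMIs left only 1038, 969, 607, 4137, 2687 and 1226 genes to test, and the counts moved down in every comparison, to 11.4%, 11.97%, 22.1%, 10.9%, 11.8% and 22.6% of these. Leaving out each library gave 8.57% to 9.19%, 8.15% to 9.05%, 11.4% to 12.4%, 12.3% to 12.97%, 12.7% to 13.2% and 17.5% to 18.7%. Without the replicate block of the pairing by library the values were 8.72%, 8.17%, 11.7%, 12.2%, 12.7% and 17.3%, and with p codes summed 9.75%, 9.44%, 12.6%, 13.6%, 13.8% and 18.4%. At least 30 nuclei per class and library could not be run for the octopus-like comparisons. Estimated correlation in camera called 1, 0, 0, 1, 0 and 0 lists, against 6, 2, 7, 9, 5 and 4, and fry called 15, 14, 12, 19, 15 and 18. The share with no type named was 2.50% at resolution 2. Of patch-seq cells, markers and 300 genes gave 11.6% T-stellate-like, 30.7% bushy-like, 1.03% molecular layer-like (13.7% with all clustering genes), 18.9% inhibitory with no type and 10.3% octopus-like, and centred genes 8.27%, 22.997%, 4.65%, 15.2% and 9.56%, and 9.04% granule-like. The causes of these moves in lists, shares and cells were not tested. A minimum of 3000 genes removed no cell and tests nothing.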

Other observations

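The Atoh7 and Fn1 cluster differed from both relay classes in genes chosen after their values were seen. Sorcs3, a sorting receptor gene available to the clustering, stood at 1242 ± 288.3 CPM (SD, n = 9 libraries), against 35.1 ± 20.7 in bushy-like and 165 ± 78.4 in T-stellate-like nuclei. Fn1, which encodes fibronectin, stood at 309 ± 123.7 CPM in the cluster.

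Oligodendrocyte-like nuclei held a cluster of 84 nuclei with Ddx60, Ifit3 and Oasl2 among its leading genes, of which 58.3% came from p1s1. A further 77 nuclei given no type had Cxcl10, a chemokine gene, among their leading genes, and 42.9% came from p1s1. A mixed cluster of 299 nuclei with Ly6c1, Hba-a2 and Hbb-bt among its leading genes came to 79.3% from p4s1. In the unipolar brush-like clusters, Homer2, a scaffold of metabotropic receptors, stood at 353.1 ± 46.7 CPM in the larger and 109.4 ± 26.3 in the smaller cluster (SD, n = 9), and the kainate receptor gene Grik1 at 204.1 ± 32.2 and 53.6 ± 29.1. None of these differences was tested.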
